A study of Mus musculus with 11 samples.

How the data were processed

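RNA was measured by RNA-seq in Ly49H+ natural killer (NK) cells sorted from the spleens of mixed bone marrow chimeric mice, with infection by mouse cytomegalovirus (MCMV) given as the treatment. Ly49H is an activating NK cell receptor that recognises an MCMV protein. Per the labels' protocols, the sort kept cells negative for TCRb and CD3e and positive for NK1.1, DX5 and Ly49H, and libraries were made with a low-input cDNA amplification kit. Wild-type (WT) cells carried CD45.1 and LDHA-deficient (KO) cells CD45.2, per the labels. The 11 libraries fall into 4 groups by title, KO D0 (3), KO D2 (3), WT D0 (2) and WT D2 (3). The days-post-infection label reads day 2 for all 11, so D0 and D2 are used here as the titles' terms and the infection status of the D0 libraries is not settled. The genotype label of the WT-titled libraries names both genotypes, and the title decided. The labels describe each sample as an individual mouse.

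The deposited values are whole-number counts per gene by Entrez ID, for 24421 genes. Per the submitters' processing notes, the tools used upstream include bcl2fastq 2.20.0.422, Trimmomatic 0.36, Salmon 0.13.1 (a further entry reads 13.1) and DESeq2 1.22.2, with build mm10. The notes as available do not give each tool's role, and the counts may be rounded estimates. Such counting can split reads unevenly between near-identical genes. Gene symbols and positions came from a RefSeq table of the same build (GRCm38.p6), which matched 24387 IDs, and the other 34 IDs held at most 0.0244% of a library's counts. Total counts ran from 19452460 to 27992092 per library, so that 3 counts, used as the floor of detection, correspond to between 0.107 and 0.154 CPM (counts scaled to an equal library total). Floors use library totals without TMM scaling and cover counting error only.

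Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust dispersion, TMM scaling, filterByExpr), which kept 13711 genes. All 11 libraries entered 1 fit with 4 group means and no covariate, leaving 7 residual degrees of freedom, because WT D0 holds 2 libraries. The 5 contrasts were KO against WT at D2 and at D0, D2 against D0 in WT and in KO, and the difference of the D2 against D0 change between genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic, and CPM are given as mean ± SD with TMM scaling. The 19 pathway lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), with camera using an estimated correlation and fry beside it. Adjusted p for lists runs over the lists within a comparison, and list members were also adjusted over the list alone. Another 7 lists held markers of other cells the sort could contain. Two-sided Fisher's exact tests compared calls within 25 Mb of Ptprc and within 10 Mb of Ldha with the remaining genes.

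The contrasts, lists, tests and the rule for named genes were fixed before the data were examined. The rule took Ldha, and for each contrast the largest rises and falls by log2 fold change (10 each way for KO against WT at D2, 8 elsewhere). These came from called genes with a mean of at least 5 CPM. They also needed no overlap between the compared groups (not asked of the difference between genotypes) and a symbol that is not a provisional name. It also took up to 3 called members per list and direction with the smallest p, or the member with the smallest p where none was called, and the most abundant member of each marker list. The text names fewer genes than the rule took, and which ones was settled after their values were seen. Genes with 3 or fewer counts in a whole group were left out, among them Il6, Sema7a, Slc17a6 and Cdh22, and Clip4 in KO. Other settings fixed at that stage were DESeq2 scaling (RLE) in edgeR, the DESeq2 1.42.0 Wald test, no filter, a filter of at least 5 mean CPM, only the compared groups' libraries, a replicate block, and leaving out each library in turn. A fit without a WT D0 library leaves 1 library in that group, so its spread comes from the other groups.

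Whether replicate numbers pair the samples was checked by correlating deviations from the group means across genes. Same-numbered KO and WT libraries correlated at 0.217, 0.198 and 0.114 at D2, and at 0.0275 and 0.410 at D0, where only 2 numbers are shared. Different-numbered ones ran from -0.193 to 0.00511 at D2. At D0 KO replicate 1 and WT replicate 2 correlated at 0.376. Deviations of the 2 WT D0 libraries mirror each other, so correlations with them are not separate evidence of pairing. In every group the deviations cancel out. Positive same-numbered values therefore pull the different-numbered ones down, and the contrast between them is partly built in. Across days same-numbered KO and WT libraries correlated at 0.218, 0.152 and 0.201 (KO D0 with WT D2) and at 0.134 and 0.162 (KO D2 with WT D0). Within a genotype the same numbers correlated across days at 0.0427, 0.0110 and 0.104 in KO and at 0.00843 and 0.159 in WT. Different numbers ran from -0.129 to 0.0807 in KO and from -0.159 to 0.114 in WT. WT and KO cells of a mixed chimera can share a mouse, but a mouse gives spleen cells once and so does not tie libraries across days, and what the numbers track is not settled. The fit without a block ignores any such ties in all 5 contrasts. The block took the number within the day for KO against WT and for the difference between genotypes, and across days for D2 against D0. No WT D0 library has number 1. Within the day KO D0 replicate 1 thus does not inform KO against WT at D0 or the difference between genotypes. The block also leaves fewer residual degrees of freedom. No pair of libraries of a group agreed within sampling noise.

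After the data were examined, the peak GC of each gene was computed as the highest GC share of any 100-nt window of its GENCODE M21 transcripts (median over coding transcripts). It was available for 93.5% of the tested genes. A GC-rich segment means a peak GC of at least 75%. A library's GC score is the median centred log2 CPM of genes with a GC-rich segment minus that of genes with a peak GC under 70%. Corrections added at that stage were a test among genes with a peak GC under 70%, an offset from a smooth of log CPM on peak and mean GC (mgcv 1.9.3), both with and without the replicate block, and the GC score as a covariate. The estimated correlation and fry with the replicate block, and a block across days for KO against WT and the difference between genotypes, were also run at that stage.

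The fits were tested on simulated data with 200 changed genes among 13711. For KO against WT at D2, 70% of the genes changed 2-fold and 20% of those changed 1.5-fold were recovered, and 4.26% of calls were false. For D2 against D0 in KO these shares were 70% and 55%, but the simulated genes kept their own D0 and D2 means. These 2 shares thus mix the planted change with the day difference and do not measure recovery of 2-fold or 1.5-fold changes. False calls were not counted there. For the difference between genotypes, 5% of the genes changed 2-fold and 1% of those changed 1.5-fold were recovered, and 14.3% of calls were false (1 call). The simulated libraries carried no replicate pairs. When genes with a GC-rich segment were lowered by 0.5 in KO D2 on the log2 scale, edgeR called 28 genes lower and 2 higher without a correction. It called 0 with the GC offset and 0 among genes with a peak GC under 70%. In the real data 1404 of 3805 genes with a GC-rich segment were called lower, so the simulation does not reproduce that pattern. Genes with a peak GC under 70% were not lowered in it. These counts therefore cannot show that either correction suits the real data. A simulated 1.5-fold rise of the interferon list was called by camera for KO against WT at D2, with 0 of the other lists called. Simulated genes were drawn independently, while the estimated correlation of that list was 0.31 in the real data. The count of 0 therefore cannot show how the preset correlation performs on correlated lists.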

Results

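The libraries profile NK cells that carry Ly49H, from the spleens of mixed bone marrow chimeras in which WT and LDHA-deficient cells share a host. LDHA is the A subunit of lactate dehydrogenase, which interconverts pyruvate and lactate. The comparisons ask how the genotypes differ under each title day, how D2 differs from D0 in each genotype, and whether that change differs between genotypes. Total counts per library ran from 19452460 to 24754212 in KO D0 (n = 3), 21902080 to 24371249 in KO D2 (n = 3), 25510842 to 27992092 in WT D0 (n = 2) and 23361983 to 27702679 in WT D2 (n = 3). The first principal component held 71.2% of the variance and the second 10.8%.

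Ldha (Entrez 16828, chromosome 7, 46842274 to 46855627, mm10) was low in every KO library and higher at D2 than at D0 in WT. It stood at 609 ± 66.2 CPM in WT D0 (SD, n = 2) and 2903 ± 179 CPM in WT D2 (n = 3), against 99.3 ± 7.16 CPM in KO D0 and 109.6 ± 7.17 CPM in KO D2 (n = 3 each). KO cells thus held 16.3% of the WT level at D0 and 3.77% at D2. The log2 fold change of KO against WT was -2.62 (SE 0.12, edgeR adjusted p = 3.8e-07) at D0 and -4.73 (SE 0.13, adjusted p = 4.1e-10) at D2. All 6 KO libraries lay between 91.1 and 114.6 CPM and all 5 WT libraries between 562 and 3100 CPM. The labels do not say which part of the gene was removed.

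**Figure D1:**
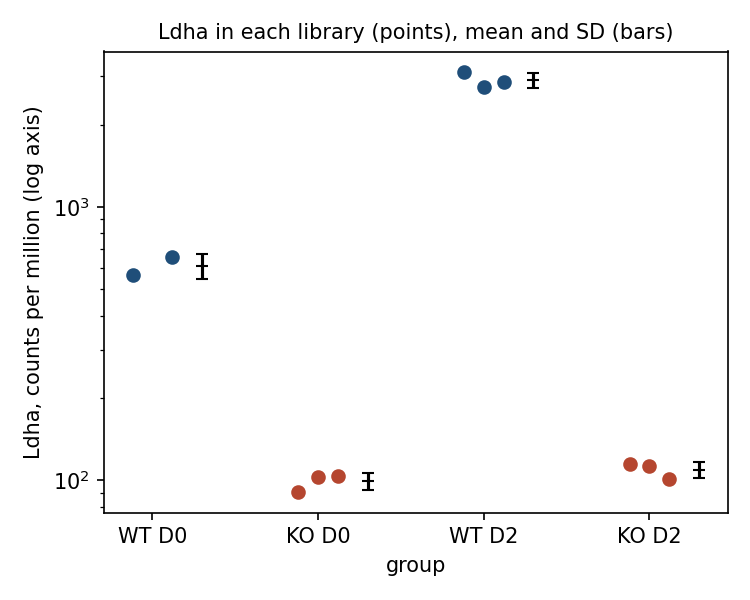
Ldha in CPM (log axis) in each library (points), by group, with the mean and SD of the group as a bar beside them. The 6 KO libraries lie between 91.1 and 114.6 CPM, below all 5 WT libraries, which reach 3100 CPM at D2.

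At D2, KO cells differed from WT cells in 2207 of 13711 genes, of which 221 were higher and 1986 lower in KO. The count of 221 was 91 and 119 without KO D2 replicates 1 and 3, and 108 and 106 without WT D2 replicates 2 and 3. It was 440 with RLE scaling (1762 lower), 697 with DESeq2 (1958 lower), 490 with only the compared groups (2025 lower), 900 with the replicate block (2544 lower) and 442 with the block across days (2283 lower), which was chosen after the data were examined. Among the genes higher in KO, Psrc1, which encodes a microtubule-associated protein, stood at 9.53 ± 1.61 CPM against 0.939 ± 0.194 in WT (log2 fold change 3.33, SE 0.31, adjusted p = 6.7e-05, n = 3 each). Cd55, which limits complement on the cell surface, was higher by 2.98 (SE 0.22), Dglucy by 2.33 (SE 0.19), Cnbd2 by 1.75 (SE 0.23), the arsenite methyltransferase gene As3mt by 1.66 (SE 0.19) and the epoxide hydrolase gene Ephx1 by 1.42 (SE 0.21) on the log2 scale. The class Ib histocompatibility genes H2-Q6 (1.41, SE 0.13) and H2-Q7 (1.28, SE 0.10) and the protease inhibitor gene Serpine2 (1.21, SE 0.16) were also higher, as was the antiproliferative gene Btg2 (2.33-fold). H2-Q6 and H2-Q7 are near-identical, so the split of reads between them is uncertain. After Ldha, the lowest log2 fold changes among the named genes were those of Pgp, which encodes phosphoglycolate phosphatase (-3.90, SE 0.65), the histone gene H2ac24 (-3.48, SE 0.50), Sdhaf1, an assembly factor of succinate dehydrogenase (-3.31, SE 0.52), and Tmem160 (-3.29, SE 0.59). Pdf (-3.22, SE 0.52), Znhit2 (-3.01, SE 0.49), Dhrsx (-2.98, SE 0.51), Ssbp4 (-2.92, SE 0.46) and the histone gene H2aj (-2.88, SE 0.43) followed. The histone genes share sequence with their copies, which leaves their counts uncertain. The highest adjusted p among the genes of this paragraph was 0.0019, for Tmem160.

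Type I interferon response genes were the only list past the threshold at D2 by camera without the replicate block (camera adjusted p = 4.5e-07, or adjusted p = 0.58 with an estimated correlation). Of 32 members 6 were higher and 1 lower in KO, or 17 higher and 1 lower adjusted over the list alone, with a median log2 fold change of 0.38. With the block, 4 more lists passed, NK effector genes, amino acid and iron uptake, NK identity and p53 targets. With the block and an estimated correlation 0 lists passed, with adjusted p = 0.35 for interferon response, 0.61 for NK effector genes, 0.36 for uptake, 0.36 for NK identity and 0.50 for p53 targets. By fry without the block interferon response (0.033) and p53 targets (0.0056) lay higher, and uptake (0.0056) and oxidative stress genes (0.0056) lower. Oxidative stress genes had 3 lower and 0 higher of 16 (0 higher and 3 lower adjusted over the list alone, median -0.05, camera adjusted p = 0.50, or adjusted p = 0.81 with an estimated correlation). Among interferon response genes Oasl2 (0.58, SE 0.11), Oas3 (0.54, SE 0.14) and the nucleic acid sensor gene Zbp1 (0.44, SE 0.11) were higher, and the nucleotide kinase gene Cmpk2 was lower (-1.52, SE 0.24). The adjusted p of Zbp1 was 0.097 without KO D2 replicate 1, 0.054 without KO D2 replicate 3, 0.086 without WT D2 replicate 2 and 0.064 without WT D2 replicate 3. That of Oas3 was 0.076 without KO D2 replicate 1, 0.060 without WT D2 replicate 2 and 0.087 without WT D2 replicate 3.

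Of 19 genes of glycolysis, 2 were lower in KO at D2 and the others were not called (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.87). Those were the lactate transporter gene Slc16a1 (-1.46, SE 0.18) and the phosphoglycerate mutase gene Pgam1 (-0.47, SE 0.11). In oxidative phosphorylation 6 of 72 members were lower (0 higher and 6 lower adjusted over the list alone, adjusted p = 0.20), Cox5a (-1.92, SE 0.17) and Ndufab1 (-1.69, SE 0.17) among them. Of its 59 members without a GC-rich segment 1 was lower and 0 higher, with a median of 0.14. The list lay higher with a camera adjusted p of 0.026 without WT D2 replicate 3. With all 11 libraries it had adjusted p = 0.92 by camera with an estimated correlation and 0.81 by fry. In DNA replication 5 of 30 were lower (0 higher and 5 lower adjusted over the list alone, adjusted p = 0.14), Mcm6 among them (-1.48, SE 0.16). In mitosis 3 of 26 were lower (0 higher and 3 lower adjusted over the list alone, adjusted p = 0.21), Ccna2 among them (-2.24, SE 0.26). Without WT D2 replicate 2 both lists lay lower past the threshold (adjusted p = 0.0083 for DNA replication and 0.0047 for mitosis), and without WT D2 replicate 1 the mitosis median was 0.03 against -0.18. With the GC offset, chosen after the data were examined, they had camera adjusted p = 0.0013 and 0.025. With an estimated correlation, all 11 libraries and no offset, both lists had camera adjusted p = 0.92.

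Of 10 genes for amino acid and iron uptake, 4 were lower in KO at D2 (0 higher and 5 lower adjusted over the list alone). These included the amino acid transporter genes Slc3a2 (-1.09, SE 0.13), Slc1a5 (-1.78, SE 0.36) and Slc7a5 (-1.21, SE 0.28). By camera the list had adjusted p = 0.064, and with the block it lay lower (adjusted p = 0.018, or adjusted p = 0.36 with an estimated correlation), while fry without the block gave an adjusted p of 0.0056. With the GC offset, chosen after the data were examined, camera gave adjusted p = 0.015. Its camera adjusted p was 0.046 without KO D0 replicate 3, 0.045 without KO D2 replicate 2 and 0.043 without WT D2 replicate 3. The adjusted p of Slc7a5 was 0.055 without KO D2 replicate 1 and 0.054 without WT D2 replicate 2.

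Of 15 p53 targets, 5 higher and 3 lower were called (7 higher and 3 lower adjusted over the list alone). The higher ones include Phlda3 (2.15, SE 0.60, edgeR adjusted p = 0.025), on chromosome 1 (start 135766085) near the CD45 gene Ptprc. It was already higher in KO at D0 (5.42, SE 0.78, edgeR adjusted p = 0.019). A gene near the locus that marks the genotypes thus counts toward the list's rise. Cyclin G1 (Ccng1, 0.82, SE 0.16), the cell cycle inhibitor gene Cdkn1a (1.07, SE 0.21) and the death receptor gene Fas (0.57, SE 0.15) were higher, and Mdm2, whose product degrades p53, was lower (-0.58, SE 0.12). By camera the list had adjusted p = 0.064 (median 0.21), and with the block it lay higher (adjusted p = 0.025, or adjusted p = 0.50 with an estimated correlation), while fry without the block gave an adjusted p of 0.0056. With the GC offset, chosen after the data were examined, its median was 0.59 (adjusted p = 3.0e-07), and Mdm2 stood at 0.0423 (adjusted p = 0.88), so its fall was lost. Its camera adjusted p was 0.046 without KO D0 replicate 3 and 0.023 without WT D2 replicate 2. The adjusted p of Fas was 0.082 without KO D2 replicate 1, 0.084 without KO D2 replicate 2, 0.056 without WT D2 replicate 1 and 0.10 without WT D2 replicate 3.

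Of 24 NK identity and maturation genes, 2 higher and 3 lower were called (2 higher and 3 lower adjusted over the list alone). The transcription factor gene Tcf7 (0.97, SE 0.26) was among those higher, and the transcription factor genes Tbx21 (-2.00, SE 0.42) and Eomes (-0.59, SE 0.19) and the receptor gene Ncr1 (-0.80, SE 0.11) were lower. By camera the list had adjusted p = 0.14 (median 0.22), and with the block it lay higher (adjusted p = 0.025, or adjusted p = 0.36 with an estimated correlation). The adjusted p of Tcf7 was 0.12 without KO D2 replicate 2, 0.085 without KO D2 replicate 3, 0.060 without WT D2 replicate 1 and 0.058 without WT D2 replicate 3. That of Eomes was 0.17 without KO D2 replicate 1, 0.13 without KO D2 replicate 2, 0.086 without KO D2 replicate 3, 0.061 without WT D0 replicate 2, 0.060 without WT D0 replicate 3, 0.23 without WT D2 replicate 2 and 0.15 without WT D2 replicate 3, and with the GC offset Eomes stood at 0.065 (adjusted p = 0.76).

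Among 16 NK effector genes edgeR called 0 at D2 (also 0 adjusted over the list alone), and 4 were higher at an unadjusted p under 0.05. The chemokine gene Ccl5 had an adjusted p of 0.055 (0.41, SE 0.13), or 0.0027 with the block. By camera the list had adjusted p = 0.064 (median 0.20), and with the block it lay higher (adjusted p = 0.018, or adjusted p = 0.61 with an estimated correlation). Its camera adjusted p was 0.046 without KO D0 replicate 3, 0.029 without KO D2 replicate 3, 0.023 without WT D2 replicate 2 and 0.043 without WT D2 replicate 3.

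The genes lower in KO at D2 were mostly genes whose transcripts hold a GC-rich segment. Of 3805 genes with one, 1404 were lower and 17 higher (36.9% lower, median log2 fold change -0.46), against 550 lower and 192 higher of the 9012 others (6.10% lower, median 0.08). The GC score was -0.64 ± 0.05 in KO D2 and 0.04 ± 0.20 in WT D2 (n = 3 each), against 0.34 ± 0.15 in KO D0 (n = 3) and 0.34 ± 0.04 in WT D0 (n = 2). Equal scores do not exclude another GC trend at D0, where KO against WT rose with mean GC (Spearman rho 0.304, against -0.058 at D2). The 207 genes with a peak GC under 55% had a median log2 fold change of -0.257 at D0 and 0.348 in the difference between genotypes. Pgp, H2ac24, Sdhaf1, Tmem160, Pdf, Znhit2, Ssbp4, H2aj, Slc16a1, Slc1a5, Slc7a5, Cox5a, Mcm6, Cmpk2, Mdm2, Tbx21 and Eomes each hold a GC-rich segment, as does Ccng1, which was higher. With the replicate block 3444 genes were called, or 2725 with the block across days. With the GC offset 1069 were higher and 1276 lower, or 1885 higher and 1667 lower with the block and the offset. Among the 6133 genes with a peak GC under 70%, 71 were higher and 183 lower, or 441 higher and 331 lower with the block, and these tests were chosen after the data were examined. With the GC score as a covariate 1 gene, Ldha, was called. The score comes from these same counts and parts all KO D2 from all WT D2 libraries. That fit therefore can hardly separate the score from genotype.

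**Figure D2:**
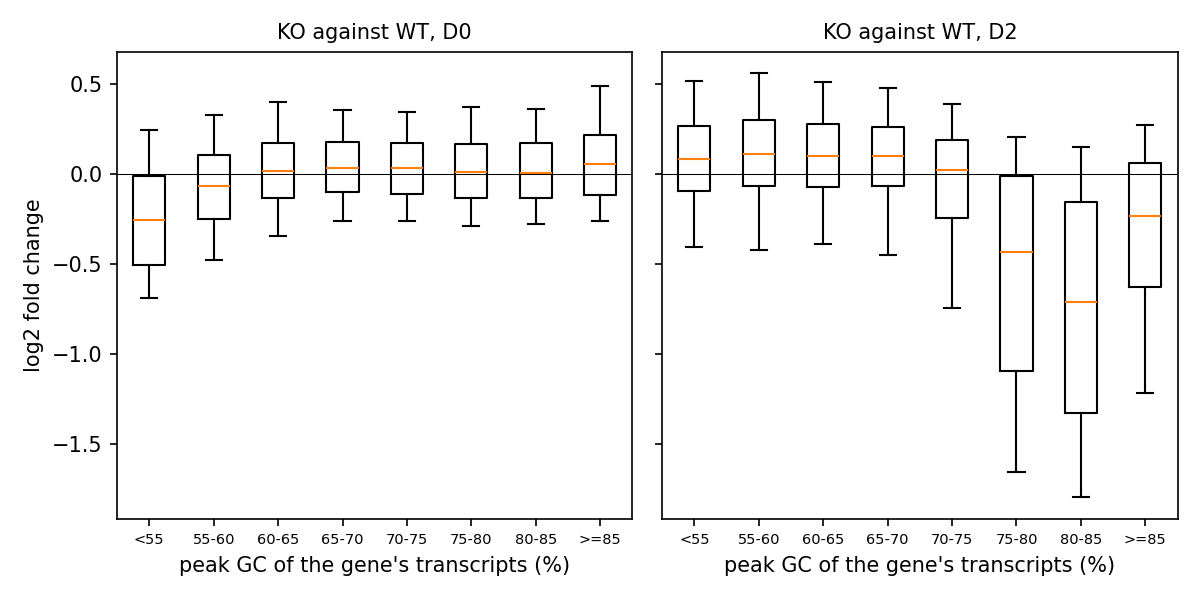
Log2 fold change of KO against WT at D0 (left) and D2 (right) by the peak GC of a gene's transcripts in percent. Boxes span the quartiles with the median as a line, whiskers the 10th to 90th percentiles, and at D2 genes with a GC-rich segment have a median of -0.46 against 0.08 in the others.

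At D0, 21 genes differed between genotypes, 13 higher and 8 lower in KO, and 597 had an unadjusted p under 0.05. The count was 38 (25 higher, 13 lower) with DESeq2 and 4 (2 higher, 2 lower) with only the compared groups. With the replicate block it was 201 (41 higher, 160 lower), so the balance turned. That block leaves KO D0 replicate 1, which has no WT partner, out of this contrast, so the libraries compared change too. With the block across days the count was 28 (17 higher, 11 lower). Serpine2 was higher in KO (log2 fold change 2.09, SE 0.20), as were H2-Q6 (1.01, SE 0.15), Btg2 (0.99, SE 0.14), H2-Q7 (0.88, SE 0.11), the mitochondrial carrier gene Sfxn2 (0.87, SE 0.14) and the RNA helicase gene Ddx39b (0.73, SE 0.11). The phosphatase gene Ptprv was lower (-2.98, SE 0.28, adjusted p = 0.00055), as were the chemokine receptor gene Cxcr4 (-1.84, SE 0.32, adjusted p = 0.048), Cdk5rap1 (-1.22, SE 0.16), Ncr1 (-0.96, SE 0.12), the interferon-inducible gene Ifi208 (-0.79, SE 0.14) and Wdfy1 (-0.63, SE 0.10). Of the 21 genes, 19 were also called at D2, all 19 in the same direction. The count fell to 4 without KO D0 replicate 2 or WT D0 replicate 2 (2 higher and 2 lower each), and to 7 (3 and 4) without WT D0 replicate 3, and the fits without a WT D0 library keep 1 library of that group. It fell to 10 (5 and 5) without WT D2 replicate 3, and to 13 (9 and 4), 11 (7 and 4) and 11 (6 and 5) without KO D2 replicates 1, 2 and 3, while without KO D0 replicate 1 or 3 the lower genes fell to 5. Of the 13 named genes, Ldha, Serpine2 and Ptprv stayed called whichever library was left out, and each of the other 10 lost its call without at least 1 library.

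The D0 calls were frequent on chromosome 1 near Ptprc (138062859 to 138175756), which encodes CD45, whose alleles mark the genotypes. Within 25 Mb of Ptprc 7 of 199 tested genes were called, against 14 of 13499 elsewhere (odds ratio 35.1, Fisher's exact p = 1.2e-08). Of the 21 genes 10 lie on chromosome 1, including Ptprv (start 135108498), Btg2 (134074865), Cxcr4 (128588199), and farther from Ptprc Serpine2 (79794317), Wdfy1 (79702262) and Ifi208 (173673628). At D2 the genes higher in KO were also frequent within 25 Mb, 14 of 199 against 207 of 13499 (odds ratio 4.86, exact p = 4.2e-06), while for the lower genes the odds ratio was 1.31 (exact p = 0.15). For either direction at D2 the odds ratio was 1.77 within 25 Mb (exact p = 0.00090) and 1.223 within 50 Mb (exact p = 0.10). Within 10 Mb of Ldha, itself left out, 20 of 140 genes were called at D2 (exact p = 0.64), and 0 of 140 by edgeR at D0.

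By camera, 4 lists lay higher in KO at D0, each with adjusted p = 0.85 with an estimated correlation. They were mitosis (median 0.32, adjusted p = 5.0e-07), oxidative phosphorylation (0.14, adjusted p = 0.00042), DNA replication (0.17, adjusted p = 0.00087) and immediate early and heat shock genes (0.30, adjusted p = 0.00089). Of their members only Btg2 was called, also adjusted over the list alone. By fry each of the 4 had an adjusted p of 0.49. With the replicate block oxidative phosphorylation was not past the threshold (adjusted p = 0.17) and the other 3 were, as were glycolysis (0.048) and the ATF4 stress response (0.019), higher, and NK identity (0.017), lower. With the block and an estimated correlation the lowest adjusted p was 0.80. Without WT D0 replicate 2, and with no block, the camera adjusted p was 0.21 for oxidative phosphorylation and DNA replication, and without KO D0 replicate 1 it was 0.38 for oxidative phosphorylation. For the immediate early list it was 0.39 without KO D0 replicate 2 and 0.50 without WT D0 replicate 3. Lists that without the block were past the threshold when 1 library was left out, and not with all 11, were glycolysis, with adjusted p = 0.017 without WT D0 replicate 3, the ATF4 list, with 0.037 without KO D0 replicate 1 and 0.028 without WT D0 replicate 3, and NK identity, lower with 0.017 without WT D0 replicate 3. Macrophage and monocyte markers lay lower in KO D0 (median -0.75, camera adjusted p = 3.6e-06, or adjusted p = 0.068 with an estimated correlation).

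In WT cells 7336 genes differed between D2 and D0, 3776 higher and 3560 lower at D2, or 7828 (4056 higher, 3772 lower) with the replicate block. Zbtb32, a transcription factor gene of activated lymphocytes, rose by 9.65 on the log2 scale (SE 0.32, adjusted p = 1.1e-09). Ly6a (9.09, SE 0.59), the cytokine gene Il10 (7.89, SE 1.09), Acod1, whose product makes itaconate (7.65, SE 0.71), the chemokine gene Cxcl10 (7.65, SE 0.41) and the interleukin-2 receptor gene Il2ra (7.54, SE 0.47) rose too, as did Ldha (2.25, SE 0.13). The falls included Clip4 (-7.43, SE 0.45), the transporter gene Slc26a11 (-7.23, SE 0.22), the egress receptor gene S1pr1 (-6.41, SE 0.27), Rhpn1 (-6.06, SE 0.53), Tmem151a (-6.01, SE 0.39), G0s2 (-5.98, SE 0.60) and Angpt1 (-5.92, SE 0.36). No gene named for D2 against D0 in WT or KO lost its call when any 1 library was left out.

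Interferon response genes rose in all 32 tested members in WT (32 higher and 0 lower adjusted over the list alone, median 3.20, camera adjusted p = 2.2e-44, or adjusted p = 0.045 with an estimated correlation). Usp18 stood at 5.57 (SE 0.17) and Ifi44 at 6.53 (SE 0.21). DNA replication rose in 29 of 30 members (29 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.7e-30, or adjusted p = 0.0497 with an estimated correlation). Mcm10, a replication initiation gene, rose by 4.48 (SE 0.21). Mitosis rose in 26 of 26 (26 higher and 0 lower adjusted over the list alone, camera adjusted p = 5.4e-26, or adjusted p = 0.080 with an estimated correlation). Cdk1, the mitotic kinase gene, rose by 3.43 (SE 0.20). MYC targets and ribosome biogenesis rose in 25 of 25 (25 higher and 0 lower adjusted over the list alone, camera adjusted p = 6.5e-21, or adjusted p = 0.0497 with an estimated correlation). Pa2g4 (2.57, SE 0.12) and Myc itself (3.35, SE 0.19) rose. Oxidative phosphorylation had 69 higher and 1 lower of 72 (70 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.3e-11, or adjusted p = 0.19 with an estimated correlation). The ATP synthase gene Atp5g3 rose by 1.53 (SE 0.12). In pyruvate dehydrogenase and the citric acid cycle 12 of 19 rose (13 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0024, or adjusted p = 0.25 with an estimated correlation). Idh3a rose by 1.46 (SE 0.11). Glycolysis had 11 higher and 4 lower of 19 (11 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0020, or adjusted p = 0.28 with an estimated correlation). The hexokinase gene Hk2 stood at 4.62 (SE 0.34), Gapdh at 2.08 (SE 0.15), Pgk1 at 1.87 (SE 0.12) and the glucose transporter gene Slc2a3 at -1.30 (SE 0.19).

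NK effector genes had 11 higher and 2 lower of 16 in WT (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00074, or adjusted p = 0.11 with an estimated correlation). The granzyme genes Gzmb (4.77, SE 0.17) and Gzmc (3.81, SE 0.25) and the perforin gene Prf1 (1.40, SE 0.13) rose, and Ccl5 fell (-1.28, SE 0.15). NK identity and maturation genes had 4 higher and 13 lower of 24 (4 higher and 16 lower adjusted over the list alone, camera adjusted p = 0.0071, or adjusted p = 0.18 with an estimated correlation). Thy1 rose (2.59, SE 0.31), and S1pr5 (-5.30, SE 0.45) and Tcf7 (-2.89, SE 0.29) fell. The ATF4 stress response list had 11 higher and 3 lower of 20 (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00051, or adjusted p = 0.11 with an estimated correlation). The asparagine synthetase gene Asns stood at 5.06 (SE 0.32). Of 10 uptake genes 7 rose (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0024, or adjusted p = 0.11 with an estimated correlation). Slc7a5 rose by 3.63 (SE 0.37). The cytokine receptor and STAT list had 14 higher and 3 lower of 22 (14 higher and 3 lower adjusted over the list alone, camera adjusted p = 6.0e-05, or adjusted p = 0.11 with an estimated correlation). Immediate early and heat shock genes had 3 higher and 11 lower of 22 (3 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.042, or adjusted p = 0.48 with an estimated correlation). Klf2 stood at -2.78 (SE 0.17). The adjusted p of that list was 0.16 without WT D0 replicate 2, 0.078 without WT D2 replicate 1, 0.056 without WT D2 replicate 3, and 0.052, 0.062 and 0.054 without KO D2 replicates 1, 2 and 3.

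In KO cells 8422 genes differed between D2 and D0, 3697 higher and 4725 lower at D2, or 8842 (3910 higher, 4932 lower) with the replicate block. Zbtb32 (9.31, SE 0.26), Ly6a (9.22, SE 0.49), Acod1 (8.00, SE 0.58), Cxcl10 (7.73, SE 0.34), the interferon-inducible gene Ifi211 (7.61, SE 0.23) and Il2ra (7.57, SE 0.39) rose. Tmem151a (-7.31, SE 0.43), Mturn (-6.50, SE 0.57), Cpne7 (-6.30, SE 0.37), Ypel3 (-6.25, SE 0.29), S1pr1 (-6.22, SE 0.26), G0s2 (-6.16, SE 0.61), S1pr5 (-6.07, SE 0.46) and Slc3a2 (-0.72, SE 0.13) fell, and Ldha was not called (0.14, SE 0.11, adjusted p = 0.28). Of the 3805 genes with a GC-rich segment 1978 were lower at D2 in KO, against 1053 in WT. With the GC score as a covariate 1862 genes were called, and the score also parts all KO D2 from all KO D0 libraries.

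Interferon response genes rose in 31 of 32 members in KO (32 higher and 0 lower adjusted over the list alone, median 3.55, camera adjusted p = 3.1e-57, or adjusted p = 0.030 with an estimated correlation). Usp18 stood at 5.66 (SE 0.14) and Ifi44 at 7.20 (SE 0.18). DNA replication had 28 higher and 1 lower of 30 (28 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.0e-25, or adjusted p = 0.077 with an estimated correlation). Mcm10 stood at 3.62 (SE 0.17). Mitosis rose in 25 of 26 (26 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.1e-20, or adjusted p = 0.10 with an estimated correlation), with Cdk1 at 3.01 (SE 0.16). MYC targets rose in 24 of 25 (25 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.9e-20, or adjusted p = 0.077 with an estimated correlation). Pa2g4 stood at 2.41 (SE 0.10). Oxidative phosphorylation had 63 higher and 2 lower of 72 (63 higher and 3 lower adjusted over the list alone, camera adjusted p = 6.7e-11, or adjusted p = 0.24 with an estimated correlation). Ndufa12 stood at 1.60 (SE 0.12). Glycolysis had 11 higher and 3 lower of 19 (11 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0016, or adjusted p = 0.31 with an estimated correlation). Hk2 stood at 3.90 (SE 0.28), Pgk1 at 1.65 (SE 0.11) and Slc2a3 at -0.79 (SE 0.17). Effector genes had 11 higher and 3 lower of 16 (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 2.7e-05, or adjusted p = 0.077 with an estimated correlation). Gzmb stood at 5.14 (SE 0.14), Gzmc at 3.82 (SE 0.21) and Prf1 at 1.56 (SE 0.11).

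NK identity and maturation genes, past the threshold in WT, were not in KO (6 higher and 12 lower of 24, 6 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.17, median -0.54), though fry gave an adjusted p of 0.00041. With an estimated correlation WT was not past it either (camera adjusted p = 0.18). The test of the difference gave this list a camera adjusted p of 0.016, or 0.59 with an estimated correlation. Uptake genes had 5 higher and 2 lower of 10 in KO (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.066), or camera adjusted p = 0.046 without KO D0 replicate 3 and 0.038 without KO D2 replicate 1, and fry gave an adjusted p of 0.00021. The citric acid cycle list had 12 higher and 1 lower of 19 (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0013, or adjusted p = 0.27 with an estimated correlation) and the ATF4 list 10 higher and 5 lower of 20 (10 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00082, or adjusted p = 0.15 with an estimated correlation). The cytokine receptor and STAT list had 12 higher and 5 lower of 22 (12 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00033, or adjusted p = 0.15 with an estimated correlation). Immediate early and heat shock genes had 3 higher and 14 lower of 22 (3 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.0083, or adjusted p = 0.34 with an estimated correlation).

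Across the 13711 genes the D2 against D0 log2 fold changes in KO and WT, which share no library, correlated at a Pearson r of 0.855 and a Spearman rho of 0.838, with a slope of 0.875 of KO on WT. With the filter of 5 mean CPM r was 0.901 and the slope 0.947. Genes are not independent replicates. Both genotypes called 6321 genes, 6212 in the same direction and 109 in opposite directions. They shared 3123 higher and 3089 lower genes, where independent calls would share 1018 and 1227.

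**Figure D3:**
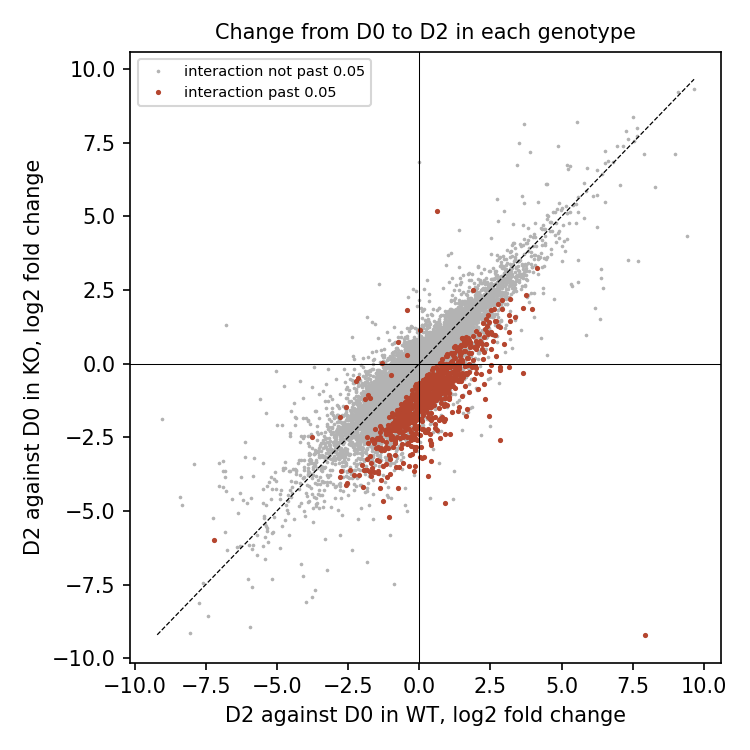
Log2 fold change of D2 against D0 in WT (horizontal) and KO (vertical) for the 13711 tested genes. Red points are the 801 genes whose change differed between genotypes, the dashed line marks equal change, and the fold changes correlate at 0.855.

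The change from D0 to D2 differed between genotypes in 801 genes, 17 with a higher and 784 with a lower value in KO. Ldha differed by -2.11 (SE 0.17, adjusted p = 0.00022). Differences above 0 were found for Cd55 (1.66, SE 0.30), Dglucy (1.61, SE 0.27), Cnbd2 (1.49, SE 0.34), Naip6 (1.36, SE 0.23), the retinoic acid receptor gene Rarg (1.28, SE 0.32), Slc26a11 (1.24, SE 0.30), Ephx1 (1.10, SE 0.29) and Serpini1 (1.09, SE 0.28). Differences below 0 were found for H2ac24 (-4.21, SE 0.73), Pgp (-4.11, SE 0.89), Scand1 (-3.50, SE 0.53), Sdhaf1 (-3.46, SE 0.74), Tmem160 (-3.32, SE 0.82), Znhit2 (-3.29, SE 0.69), Pdf (-3.25, SE 0.73), the histone gene H2ac11 (-3.24, SE 0.71), the cyclin gene Ccna2 (-2.30, SE 0.39) and Slc3a2 (-1.26, SE 0.20). By camera, DNA replication (median -0.31, adjusted p = 0.00076), mitosis (-0.50, adjusted p = 0.00011) and amino acid and iron uptake (-0.42, adjusted p = 0.014) lay lower. For mitosis KO against WT had a median of 0.32 at D0 and -0.18 at D2 (camera adjusted p = 0.21 at D2). For DNA replication these were 0.17 and -0.13 (camera adjusted p = 0.14 at D2). Much of both differences thus comes from higher KO values at D0, where WT holds 2 libraries. Interferon response (0.32, adjusted p = 2.1e-05) and NK identity (0.31, adjusted p = 0.016) lay higher, and each of the 5 lists had adjusted p = 0.59 with an estimated correlation. By fry uptake and oxidative stress genes lay lower (adjusted p = 0.030 and 0.030), the latter with 3 of 16 called lower (0 higher and 3 lower adjusted over the list alone) and camera adjusted p = 0.45. The other 4 lists had fry adjusted p from 0.14 to 0.26. Called members were 3 lower for DNA replication (0 higher and 7 lower adjusted over the list alone), 2 lower for mitosis (0 higher and 3 lower adjusted over the list alone), 2 lower for uptake (0 higher and 5 lower adjusted over the list alone) and 1 lower for interferon response (0 higher and 0 lower adjusted over the list alone). In NK identity edgeR called 0, with 4 higher and 3 lower at an unadjusted p under 0.05. NK effector genes lay higher with the block (camera adjusted p = 0.020, or adjusted p = 0.71 with an estimated correlation), against adjusted p = 0.11 without it. With the replicate block, which leaves KO D0 replicate 1 out of this contrast, 2616 genes were called (619 higher and 1997 lower). With the block across days 1858 were called (139 higher, 1719 lower), and with DESeq2 92 were higher and 1069 lower. Of the genes called without the block, 592 of the 784 lower and 1 of the 17 higher genes hold a GC-rich segment.

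Each left-out library moved the count of 801 by more than 1.5 times. It was 4 and 190 without WT D0 replicates 2 and 3, fits that keep 1 WT D0 library and take its spread from the other groups. It was 1418, 149 and 506 without KO D0 replicates 1, 2 and 3. It was 121, 119 and 270 without KO D2 replicates 1, 2 and 3, and 1436, 285 and 117 without WT D2 replicates 1, 2 and 3. The 17 higher genes became 0 and 4 in the same order for WT D0, 87, 4 and 11 for KO D0, 3, 4 and 6 for KO D2, and 32, 6 and 4 for WT D2. The remaining calls were lower genes, and without WT D0 replicate 2 the unadjusted p was under 0.05 in 2201 genes. Of the 19 genes named for this difference, Ldha, Cd55, Dglucy, Naip6, H2ac24, Scand1, Ccna2 and Slc3a2 stayed called in each fit that keeps both WT D0 libraries. The other 11 lost their call in at least 1 of those fits, and without WT D0 replicate 2 all but Ldha did. Without WT D2 replicate 1 the camera adjusted p was 0.077 for DNA replication and for mitosis, without WT D0 replicate 3 it was 0.058 for uptake, and without WT D0 replicate 2 it was 0.15 for NK identity. For lists not past the threshold with all 11 libraries and no block it was, for NK effector genes, 0.039 without KO D0 replicate 2, 0.036 without KO D2 replicate 3 and 0.018 without WT D0 replicate 3, and for immediate early and heat shock genes 0.012 without KO D0 replicate 3, 0.0033 without WT D0 replicate 2 and 0.034 without WT D2 replicate 1.

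Markers of other cell types were measured in all groups. The hemoglobin gene Hbb-bs stood at 141 ± 177 CPM in KO D0 (n = 3) and 205 ± 185 in WT D0 (n = 2), against 48.1 ± 32.9 in KO D2 and 58.0 ± 60.3 in WT D2 (n = 3 each). Itgax, the most abundant gene of the dendritic cell list, stood at 301 ± 31.8 CPM in KO D2 and 215 ± 9.02 in WT D2, and NK cells express it too. Camera adjusted p for KO against WT at D2 was 0.52 for T cell, 0.52 for erythroid and platelet, 0.56 for B cell, 0.56 for macrophage and monocyte, 0.56 for dendritic cell, 0.56 for ILC1 and 0.92 for neutrophil markers. Itgax was the only member of these lists called in that comparison. For D2 against D0 camera adjusted p ran from 0.30 to 0.37 for these lists in WT and was 0.75 for each in KO. By fry all 7 lay lower at D2 in WT, from adjusted p = 0.0046 for dendritic cell to 0.022 for B cell markers, and in KO the dendritic cell (0.013) and ILC1 lists (0.028) did. Members called lower at D2 were, in WT and KO, 5 and 3 for macrophage and monocyte, 4 and 5 for dendritic cell, 4 and 4 for ILC1, 1 and 5 for neutrophil, 2 and 4 for erythroid and platelet, 2 and 1 for B cell and 1 and 1 for T cell markers. Higher at D2 were 1 and 1 for macrophage and monocyte, 1 and 1 for dendritic cell, 2 and 2 for ILC1 and 1 and 2 for T cell markers.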

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

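The tests of GC-rich segments and of other splits of the libraries were chosen only after the results were seen, as was the weighing of alleles linked to Ptprc, whose position test was itself fixed before the data were examined. What thinning to equal depth should show was set down after the imbalance but before the thinned counts were seen, and leaving out 1 library was fixed before the data were examined.

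The D2 against D0 change differed between KO and WT in 801 genes by the test of the difference itself. Ldha differed by -2.11. Positive differences were 1.66 for Cd55, 1.61 for Dglucy, 1.49 for Cnbd2, 1.36 for Naip6, 1.28 for Rarg, 1.24 for Slc26a11, 1.10 for Ephx1 and 1.09 for Serpini1. Negative differences were -4.21 for H2ac24, -4.11 for Pgp, -3.50 for Scand1, -3.46 for Sdhaf1, -3.32 for Tmem160, -3.29 for Znhit2, -3.25 for Pdf, -3.24 for H2ac11, -2.30 for Ccna2 and -1.26 for Slc3a2. List medians were -0.31 for DNA replication, -0.50 for mitosis, 0.32 for interferon response, -0.42 for amino acid and iron uptake and 0.31 for NK identity. With an estimated correlation each of these lists had camera adjusted p = 0.59. For DNA replication and mitosis KO against WT had medians of 0.17 and 0.32 at D0, against -0.13 and -0.18 at D2. Without 1 library outside WT D0 the count ran from 117 to 1436, and it was 4 and 190 without WT D0 replicates 2 and 3, fits that keep 1 WT D0 library. Without WT D0 replicate 2 each gene named here except Ldha lost its call.

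Lower calls outnumbered higher calls in KO at D2, 1986 against 221 (1958 against 697 with DESeq2), and the falls tracked GC-rich segments. The tables argue against depth, since thinning all libraries to the smallest total left 1994 lower genes, and against a change tied only to the 5′ end, since genes whose segment lies only beyond the first 300 nt differed from genes with a peak GC under 70% by -0.49 (median log2 fold change, replicate block). Uneven recovery of transcripts with a GC-rich segment may account for the imbalance. Among genes with a peak GC under 70% 42.9% of calls were lower with the replicate block, though 72.0% were lower without the block. Scaling ran over all genes, and these genes kept a median log2 fold change of 0.10 with and without the block. The balance of calls among them may therefore partly reflect the scaling and cannot decide the question. With the GC offset 1276 were lower and 1069 higher, or 1667 and 1885 with the block, but the offset removes any difference that follows GC, whatever its cause. All 3 KO D2 libraries have GC scores from -0.69 to -0.61, below the lowest WT D2 score of -0.19, so the design does not separate such recovery from an effect of genotype on these transcripts, which stays open and untested.

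Of the 10 calls between genotypes on chromosome 1 at D0, 7 lay within 25 Mb of Ptprc, and Serpine2, Wdfy1 and Ifi208 lay farther away. Of the 10 called genes on chromosome 1, 2 hold a GC-rich segment, against 3805 of the 12817 tested genes with a peak GC. With only 10 genes this share cannot decide whether uneven recovery of GC-rich transcripts adds to the calls. At D0 the 3805 genes had a median log2 fold change of 0.014, against 0.019 in the others. Alleles linked to Ptprc, which differ between CD45.1 and CD45.2 cells, may account for calls within 25 Mb, with an odds ratio of 35.1 (95% interval 11.8 to 94.2). The 3 farther calls are left unexplained. Of these, Serpine2 (start 79794317) and Wdfy1 (79702262) lay close together. D0 calls also lay close together on chromosome 17, H2-Q6 (start 35424850), H2-Q7 (35439140) and Ddx39b (35241746). The same held for Ncr1 (4337715) and Cox6b2 (4751792) on chromosome 7, and Sfxn2 (46573325) and Col17a1 (47646341) on chromosome 19. Cdk5rap1 (chromosome 2), 9530053A07Rik (chromosome 7, 28129466) and Trp53cor1 (chromosome 17, 29057474) had no other D0 call this close. The cause of this closeness was not tested. Whether any of the genes of this paragraph also differ through loss of LDHA stays open and untested.

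Interferon response genes lay higher in KO at D2. A rise that only mirrors the fall of GC-rich genes is argued against, since the list's members with a peak GC under 70% had a median 0.28 above that of all such genes (camera adjusted p = 5.2e-07 among those genes). A call decided by 1 library is argued against by medians from 0.28 to 0.46 and a highest adjusted p of 3.3e-05 without 1 library. With an estimated correlation the adjusted p was 0.58, so a shift shared by correlated genes stays open, as does an effect of genotype, which was not tested apart from it.

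Of the 10 splits of the 6 D2 libraries 1, the real one, gave 2207 calls and the highest other 0 by edgeR (at most 1555 genes at an unadjusted p under 0.05), and the 3 other splits that part all 3 same-numbered pairs also gave 0, but 10 splits are too few for a share under 0.05. For D2 against D0 in KO, 1 of 10 splits of the 6 libraries, the real one, gave 8422 calls and the highest other 0 by edgeR (at most 456 genes at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05.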

How the results depend on the processing

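Settings that use GC content, and the block across days, estimated correlation and fry with the replicate block, were chosen only after the results were seen, and all others before. For counts of called genes, each setting that moved the total, the higher or the lower genes by over 1.5 times is given here, and the cause was not tested unless stated. For KO against WT at D2 the count was 2202 (440 higher, 1762 lower) with RLE scaling, 2655 (697 higher, 1958 lower) with DESeq2, 2515 (490 higher, 2025 lower) with only the compared groups (fewer libraries), 3444 (900 higher, 2544 lower) with the replicate block and 2725 (442 higher, 2283 lower) with the block across days. It was 2345 (1069 higher, 1276 lower) with the GC offset, 3552 (1885 higher, 1667 lower) with the block and the offset, and 1 (0 higher, 1 lower) with the GC score as a covariate (1516 genes at an unadjusted p under 0.05). Among genes with a peak GC under 70% (fewer genes tested) it was 254 (71 higher, 183 lower), or 772 (441 higher, 331 lower) with the block. It ran from 1574 to 2408 without 1 library.

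For KO against WT at D0 the count was 38 (25 higher, 13 lower) with DESeq2, 11 (6 higher, 5 lower) with the filter of 5 mean CPM, and 4 (2 higher, 2 lower) with only the compared groups. With the block, which leaves KO D0 replicate 1 out of this contrast, it was 201 (41 higher, 160 lower). It was 72 (34 higher, 38 lower) with the block and the offset and 14 (8 higher, 6 lower) among genes with a peak GC under 70%. With the block among those genes it was 264 (39 higher, 225 lower). It ran from 4 to 22 without 1 library.

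For D2 against D0 in WT the count was 3435 (1961 higher, 1474 lower) among genes with a peak GC under 70% and 3622 (2031 higher, 1591 lower) with the block among them, and 6167 to 7669 without 1 library. In KO it was 1862 (1153 higher, 709 lower) with the GC score as a covariate, 3704 (2238 higher, 1466 lower) among genes with a peak GC under 70%, 3904 (2356 higher, 1548 lower) with the block among them, and 7612 to 8512 without 1 library. For the difference between genotypes it was 495 (20 higher, 475 lower) with RLE scaling, 1161 (92 higher, 1069 lower) with DESeq2, 2616 (619 higher, 1997 lower) with the block and 1858 (139 higher, 1719 lower) with the block across days. It was 383 (110 higher, 273 lower) with the GC offset, 2142 (972 higher, 1170 lower) with the block and the offset, 24 (3 higher, 21 lower) among genes with a peak GC under 70%, and 457 (260 higher, 197 lower) with the block among them. It ran from 4 to 1436 without 1 library, where the fits without a WT D0 library keep 1 library in that group. With the GC score as a covariate edgeR called 0 genes for it, with 1175 at an unadjusted p under 0.05. With that covariate Ldha stood at -2.14 (adjusted p = 0.061). In KO its D2 against D0 change, not called under any setting, stood at -0.0704 with the GC offset and -0.0709 with the block and the offset. Its other results kept their direction and call.

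The GC score comes from these same counts and parts all KO D2 (-0.69 to -0.61) from all WT D2 libraries (-0.19 to 0.20). Fold changes with it as a covariate are therefore poorly determined, and their signs show no direction. With the GC score as a covariate these log2 fold changes changed sign for KO against WT at D2: Pgp (0.65), H2ac24 (0.19), Sdhaf1 (0.14), Tmem160 (1.14), Pdf (0.53), Znhit2 (0.37), Dhrsx (0.66), Ssbp4 (0.47), H2aj (0.41), Slc1a5 (1.09), Slc7a5 (0.81), Ccng1 (-0.068), Tbx21 (1.21) and Eomes (0.69). The same held for Slc3a2 (0.29) in D2 against D0 in KO, and for Pgp (0.61), Sdhaf1 (0.15), Tmem160 (1.25), Znhit2 (0.22) and Pdf (0.61) in the difference between genotypes. For KO against WT at D2, Mdm2 stood at 0.0423 with the GC offset and 0.0529 with the block and the offset, and Eomes at 0.065 and 0.068. No named gene changed sign under the settings fixed beforehand, where RLE scaling kept 152 of 156 named values on their side of the threshold and DESeq2 154 of 156. The block changed the call of 1 of 156, Ccl5 at D2, and the block across days that of 1 of 75, the same. RLE scaling moved the median log2 fold change of all genes by 0.108 for D2 against D0 in KO and 0.104 for the difference between genotypes, and by 0.0925 for KO against WT at D2.

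Among lists, all 95 results kept their side of the threshold under RLE scaling, and 32 of 95 were past the threshold only with the preset correlation. The block changed the call of 9 of 95. These were the 4 lists at D2 and NK effector genes in the difference between genotypes, and at D0 glycolysis (0.048), ATF4 (0.019) and NK identity (0.017), which passed, and oxidative phosphorylation (0.17), which did not. With the block and an estimated correlation the adjusted p was 0.80 for these D0 lists that passed.

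For KO against WT at D2 without the filter on low counts, the camera adjusted p was 0.020 for DNA replication, 0.042 for mitosis, 0.032 for NK effector genes, 0.017 for uptake and 0.042 for p53 targets. With the block and the offset it was 0.0025 for DNA replication, 0.020 for mitosis, 0.040 for MYC targets, 0.0048 for uptake and 1.0e-08 for p53 targets. With an estimated correlation, the filter and neither block nor offset, it was 0.92 for DNA replication, mitosis and MYC targets. It was then 0.63 for NK effector genes and 0.58 for uptake and p53 targets. By fry with the block, 9 lists passed at D2, 4 higher and 5 lower.

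The direction of the test turned for the cytokine receptor and STAT list at D2 with the block among genes with a peak GC under 70% (7 members, median 0.25), for immediate early and heat shock genes at D2 among genes with a peak GC under 70% (3 members, median 0.68, or 0.68 with the block), and for oxidative phosphorylation at D0 with the block and the offset (0.022). The odds ratio near Ptprc for either direction at D2 was 1.223 within 50 Mb. The correlation of responses was 0.901 with the filter of 5 mean CPM, and the slope of KO on WT was 0.947. At these depths a gene needs at least 0.154 CPM, here without TMM scaling, to exceed 3 counts in the library with the lowest total.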

Other observations

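In the lists below no test was chosen after the results were seen. In WT, 7 of 9 pentose phosphate genes rose from D0 to D2 (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0069, or adjusted p = 0.080 with an estimated correlation), and in KO 7 higher and 1 lower were called (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0070, or adjusted p = 0.077 with an estimated correlation). Fatty acid synthesis genes had 4 higher and 1 lower of 10 in WT (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.68) and 4 higher and 2 lower in KO (4 higher and 2 lower adjusted over the list alone, adjusted p = 0.89), and the desaturase gene Scd2 fell by 3.84 in WT and fell by 3.25 in KO on the log2 scale. Sterol synthesis genes had 9 higher and 1 lower of 21 in WT (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.15) and 6 higher and 4 lower in KO (6 higher and 4 lower adjusted over the list alone, adjusted p = 0.32), with Idi1 at 2.43 (SE 0.27) in WT and 2.18 (SE 0.23) in KO. Of 15 p53 targets 4 higher and 3 lower were called in WT (4 higher and 3 lower adjusted over the list alone, adjusted p = 0.65), with Fas at 2.45 (SE 0.19), Cdkn1a at 3.19 (SE 0.27) and Sesn1 at -3.12 (SE 0.16), and in KO 5 higher and 5 lower were called (5 higher and 5 lower adjusted over the list alone, adjusted p = 0.89) and these stood at 3.13 (SE 0.17), 3.20 (SE 0.23) and -3.24 (SE 0.15).

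Hypoxia response genes outside glycolysis had 6 higher and 5 lower of 18 in WT (6 higher and 5 lower adjusted over the list alone, adjusted p = 0.65) and 5 higher and 8 lower in KO (5 higher and 8 lower adjusted over the list alone, adjusted p = 0.75), with the cytokine gene Mif at 2.60 (SE 0.17) in WT and the mitophagy receptor gene Bnip3l at -2.52 (SE 0.13). Oxidative stress genes had 7 higher and 4 lower of 16 in WT (median 0.41, 7 higher and 4 lower adjusted over the list alone, adjusted p = 0.45) and 4 higher and 5 lower in KO (median -0.08, 4 higher and 5 lower adjusted over the list alone, adjusted p = 0.83), with the thioredoxin gene Txn1 at 2.05 (SE 0.15) and the catalase gene Cat at -1.10 (SE 0.15) in WT. In KO, Mif stood at 2.42 (SE 0.14), Bnip3l at -2.26 (SE 0.12), Txn1 at 1.90 (SE 0.13) and Cat at -1.02 (SE 0.14).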
